A study of Homo sapiens with 6 samples.

How the data were processed

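RNA-seq read counts were analysed for 6 libraries of A172 cells, 2 in each of 3 groups defined by the transfected siRNA. Per the labels' protocols, total RNA was extracted with a miRNeasy kit and libraries were made with the Lexogen SENSE mRNA kit V2. The values deposited by the authors are estimated counts of reads per gene (RSEM expected counts, rounded), and all of them are whole numbers. Per the submitters' processing notes, RSEM 1.2.3 and edgeR were used and the build was hg19, with no role given for either tool. Per the file headers, each row is a group of UCSC hg19 transcripts. The aligner, the strand setting and the rounding are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner are not separated with certainty, and reads shared between near-identical genes are divided by a model, so such genes are uncertain.

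The file held 20514 rows with 65739 transcript IDs. All 6 columns matched a library by its labels. Counts were used as deposited, since rounding left them as they were. Genes were kept by edgeR's filterByExpr with its settings of 10 reads and a total of 15, which left 14711. Library sizes were scaled with TMM factors of 0.894 ± 0.010 (SD, n = 2) for siControl, 1.10 ± 0.0043 for siADAR1 and 1.02 ± 0.0064 for the combined knockdown. A single model with a mean per group was fitted to the 6 libraries, which leaves 3 residual degrees of freedom, and the 3 comparisons between groups were tested with edgeR's two-sided quasi-likelihood F test. The biological coefficient of variation was 0.0626 and the prior degrees of freedom 8.58. Adjusted p-values are by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The standard error of a log2 fold change was taken from its F statistic. Abundance is the average log2 CPM of edgeR with a prior count of 2. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for the plots.

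The totals per library ran from 20291057 to 29508632 reads and set the counting error, which is only a part of the spread between replicates. The test was tried on simulated counts with the real genes, means and library sizes and 200 changed genes. For siADAR1 against siControl, it called 63 of 100 genes changed 1.5-fold and 82 of 100 changed 2-fold in the right direction, and 22 unchanged genes, of 14711. For the combined knockdown against siADAR1 it called 64 of 100 and 85 of 100, and 14 unchanged genes. No change was simulated for the combined knockdown against siControl, where 10 genes were called. Reads without molecular identifiers are not independent molecules, so depth speaks for counting error only.

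Genes moving in opposite directions in comparisons that share libraries were set beside 100 simulated data sets with no effect, beside the overlap of independent lists, and beside covariances in which each comparison used its own library of the shared group. The share of reads in the 100 most abundant genes and the genes with at least 10 reads were computed per library, the latter after thinning to the smallest total of 20291057 reads.

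The following choices were made before the data were examined. The genes to be named were ADAR, STAU1, STAU2 and ADARB1, and in each comparison the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, an average log2 CPM of at least 3 and no overlap between the libraries of the groups. Members of 28 gene lists with the smallest adjusted p, and 8 genes with the largest reversal, were to be named as well. Because the rows hold no gene names and an annotation linking UCSC hg19 IDs to gene symbols was not used here, only 4 IDs are printed, those ranking first in either direction for siADAR1 against siControl and for the combined knockdown against siADAR1. The tests of the 28 lists, which covered interferon, stress, apoptosis, decay, cell cycle and cell type genes, were not run for the same reason, and neither was the check of the targeted genes. The RefSeq gene table of assembly GRCh38.p14 lists a few UCSC IDs among its synonyms. It matched 4 rows, 1 of them with the version number, and these are reported as other observations. No coordinates of that assembly are printed, since it is not the build of the file.

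The alternatives tried were DESeq2 size factors or library totals in place of TMM, no filter on low counts, an average log2 CPM of at least 3, DESeq2, limma-voom, the replicate letter as a block, each library left out in turn, only the 4 libraries compared, and edgeR glmTreat against a 1.5-fold change. Thinning and a normalization of each library against abundance by loess (span 0.3) were chosen after seeing the data. A group with Staufen1 siRNA alone was not analysed here, so effects of that siRNA are measured only on top of the ADAR1 siRNA.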

Results

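RNA-seq profiles of A172 cells, an established human glioblastoma line, were compared in 3 groups of 2 libraries each. The groups received a control siRNA (siControl), an siRNA against ADAR1 (siADAR1), or siRNAs against ADAR1 and Staufen1 together, called the combined knockdown here. ADAR1 is an enzyme that deaminates adenosine to inosine in double-stranded RNA, and Staufen1 (STAU1) is a double-stranded RNA-binding protein with a role in mRNA decay. Per the labels, the series examined how transcript levels changed when ADAR1, or ADAR1 and STAU1, were knocked down. The labels' treatment text is the same for every library. It also describes a plasmid coding for HA-tagged STAU1 given the day after the siRNA and does not mention the Staufen1 siRNA, so the groups are named here by their transfection labels alone.

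The siControl libraries held 20291057 (replicate a) and 24739438 (replicate b) estimated reads. The siADAR1 libraries held 25145835 and 29508632, and the combined knockdown libraries 24517904 and 28167312. Of 20514 genes, each a row of UCSC hg19 transcripts, 14711 (71.7%) had enough reads to be tested. The replicates of a group differed by more than sampling noise. The chi-square statistic per degree of freedom was 9.91 for siControl, 4.22 for siADAR1 and 3.59 for the combined knockdown, so no library was taken as a copy of another, although technical repeats can also exceed sampling noise. Across genes, which are not independent replicates, Pearson's r of log2 CPM between the replicates was 0.988, 0.994 and 0.992 in the same order. Between groups, r was 0.945 to 0.949 for siControl against siADAR1 and 0.957 to 0.963 for siControl against the combined knockdown. It was 0.972 to 0.975 for siADAR1 against the combined knockdown. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

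The deposited rows carry UCSC transcript IDs and the files do not pair them with gene names, and an annotation that links such IDs to symbols was not used here. The levels of ADAR and STAU1 in each library, which would check the knockdown labels, were therefore not analysed here. Genes are described below by how they behaved and by how abundant they were, with 4 of them given by the first ID of their row.

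Reads were spread over more genes in both knockdown groups than in siControl. The 100 most abundant genes took 31.0% ± 0.509 (SD, n = 2) of the reads in siControl, 25.1% ± 0.0189 (SD, n = 2) in siADAR1 and 27.3% ± 0.259 (SD, n = 2) in the combined knockdown. The most abundant gene, which was the same in all 6 libraries, took 5.18% ± 0.359, 3.59% ± 0.00502 and 3.69% ± 0.111 (SD, n = 2 each). With every library thinned at random to 20291057 reads, genes with at least 10 reads numbered 13751.5 ± 6.4 (SD, n = 2) in siControl. They numbered 14165 ± 17 (SD, n = 2) in siADAR1 and 14053 ± 18 (SD, n = 2) in the combined knockdown. Both libraries of each knockdown group lay beyond both siControl libraries in these measures. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, so no p-value is given for them.

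**Figure D1:**
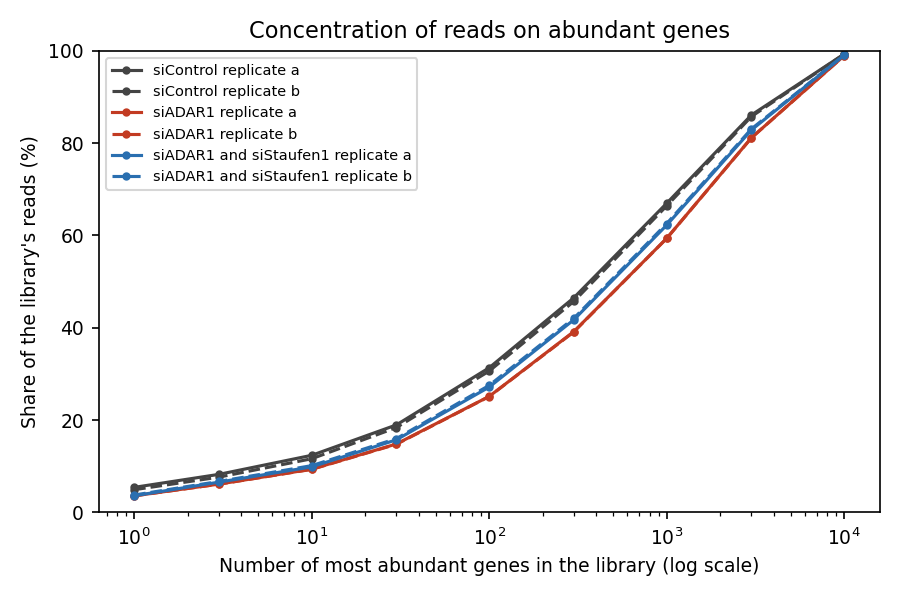
Share of each library's reads (%) taken by its most abundant genes, against the number of genes on a log scale, with 1 line per library (solid for replicate a, dashed for replicate b). At 100 genes the siControl lines lie highest (means of 31.0%, 27.3% and 25.1% for siControl, the combined knockdown and siADAR1).

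The first comparison asked what the siRNA against ADAR1 changed. With siADAR1, 4847 genes rose and 4365 fell against siControl by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, which is 62.6% of the genes tested. Among them, 1978 rose and 890 fell at least 2-fold, and 3088 rose and 455 fell at least 2-fold when scaled to library totals. The effect differed with abundance. In the most abundant quartile of genes (average log2 CPM of 5.55 or more), 53.2% fell and 26.0% rose, with a median log2 change of -0.21, whereas under scaling to library totals 30.8% fell, 44.0% rose and the median turned to 0.09. In the quartile of genes just below the middle of the abundance range (log2 CPM 1.72 to 3.84), 42.9% rose and 22.2% fell, with a median of 0.23, and under library totals 57.9% rose and 12.1% fell, with a median of 0.53.

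The 10 largest rises among genes with an average log2 CPM of at least 3 ran from 3.67 to 4.83 on the log2 scale, and the 10 largest falls from -3.49 to -4.75. The largest rise was that of the gene whose first ID is uc002gka.3, a row of 4 transcripts. It went from 0.793 ± 0.021 CPM in siControl to 22.8 ± 0.67 CPM in siADAR1 (SD, n = 2 each). Its log2 fold change was 4.83 (SE 0.17), higher in both siADAR1 libraries, with an adjusted p of 5.71e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest fall was that of uc001kmo.3, a row of 3 transcripts, from 20.7 ± 1.3 CPM to 0.752 ± 0.25 CPM (SD, n = 2 each). Its log2 fold change was -4.75 (SE 0.18), lower in both libraries, with an adjusted p of 1.31e-09 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

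The balance of rises and falls depended on the scaling. With library totals in place of TMM factors, 7095 genes rose and 2406 fell, so that rises made up 74.7% of the calls against 52.6% with TMM. The median log2 fold change of all genes shifted by 0.30 between these scalings in this comparison, by 0.18 for the combined knockdown against siControl and by -0.12 for the combined knockdown against siADAR1. When the test required a change beyond 1.5-fold (edgeR glmTreat), 2296 genes rose and 1307 fell.

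The second comparison set the combined knockdown against siControl. Here 4224 genes rose and 3798 fell by edgeR's quasi-likelihood test, 54.5% of the genes tested. At least 2-fold, 1426 rose and 544 fell, against 2001 and 332 under library totals. As with siADAR1 alone, abundant genes leaned to falls: in the most abundant quartile 47.5% fell and 25.7% rose, with a median of -0.15, and under library totals 29.5% fell, 38.3% rose and the median turned to 0.04. The 10 largest rises ran from 3.27 to 4.95 on the log2 scale, and all 10 of those genes had also risen with siADAR1 alone. Of the 10 largest falls, -2.88 to -6.75, 8 genes had also fallen with siADAR1 alone, 1 had risen and 1 was not called. Those 8 falls with siADAR1 alone ran from -4.28 to only -0.41, the latter in a gene at -3.43 with the combined knockdown. A shared call therefore does not mean a change of similar size. The fall of -6.75 rests on 2 and 6 reads in the combined knockdown libraries.

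Most genes called with siADAR1 were called the same way with the combined knockdown. There were 3310 genes higher and 2883 lower than siControl in both, where independent lists would share 1392 and 1127. These comparisons share the siControl libraries, and simulated data with no effect in any group gave at most 4 and 2 such genes in 100 data sets. Such data hold few calls at all (means of 3.44 and 3.2 genes in these comparisons), so a small overlap was bound to follow. The covariance of the log2 fold changes across genes was 0.481 against a simulated 0.0258, a difference of 0.455. With a separate siControl library for each comparison it was 0.438 or 0.430. The correlation across genes was 0.754 against 0.528 in the simulated data, where all variation is noise, so these correlations do not show what share is chance. Scaling to library totals again moved the split of the calls, to 5741 genes higher and 2349 lower, with rises making up 71.0% of the calls against 52.7% with TMM. With glmTreat at 1.5-fold, 1544 rose and 711 fell.

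The third comparison asked what changed when the Staufen1 siRNA was added to the ADAR1 siRNA. Against siADAR1, 3196 genes rose and 3170 fell in the combined knockdown by edgeR's quasi-likelihood test, 43.3% of the genes tested. At least 2-fold changes were 467 rises and 562 falls, or 361 rises and 733 falls under library totals. The 10 largest falls ran from -2.60 to -6.26 on the log2 scale and the 10 largest rises from 2.33 to 3.47. The largest fall was that of uc002xua.3, a row of 7 transcripts, which stood at 213 ± 0.87 CPM in siControl, 256 ± 0.74 CPM in siADAR1 and 3.32 ± 0.22 CPM in the combined knockdown (SD, n = 2 each). Its log2 fold change against siADAR1 was -6.26 (SE 0.080), lower in both libraries, with an adjusted p of 6.04e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Against siControl, uc002xua.3 was higher by 0.27 (SE 0.055) with siADAR1 alone, with an adjusted p of 0.00117 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and this call ended when a change beyond 1.5-fold was required.

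The largest rise against siADAR1 was that of uc003okx.2, a row of 5 transcripts. It stood at 35.9 ± 2.9 CPM in siControl, 1.33 ± 0.091 CPM in siADAR1 and 14.8 ± 0.22 CPM in the combined knockdown (SD, n = 2 each). Its log2 fold change was 3.47 (SE 0.13), higher in both libraries, with an adjusted p of 8.23e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This gene fell by 4.75 on the log2 scale with siADAR1 alone and remained lower than siControl by a log2 change of -1.27 in the combined knockdown. The genes uc002gka.3 and uc001kmo.3 moved in the same way towards siControl, by -2.62 and 3.45 against siADAR1, and still differed from siControl by 2.22 and -1.30. Scaling to library totals changed the split here too, to 2200 rises and 4411 falls, with rises making up 33.3% of the calls against 50.2% with TMM. With glmTreat at 1.5-fold, 448 rose and 571 fell.

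**Figure D2:**
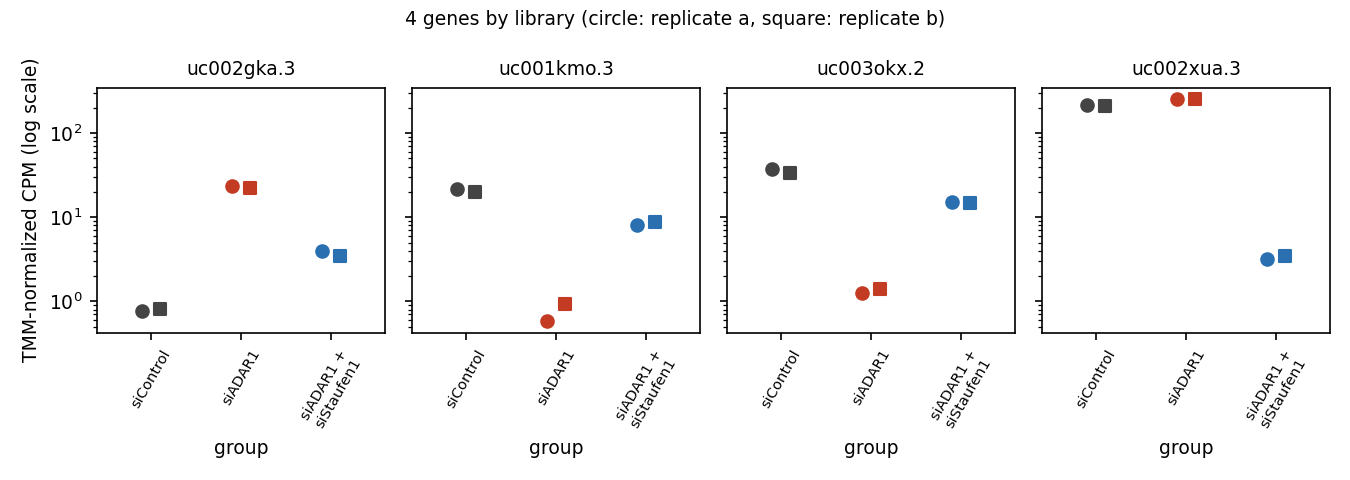
TMM-normalized CPM on a log scale of the 4 genes named by their first UCSC ID, with 1 point per library (circle for replicate a, square for replicate b). The first 3 genes lie between their siControl and siADAR1 levels in the combined knockdown, and uc002xua.3 drops from 256 CPM in siADAR1 to 3.32 CPM.

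The genes changed by siADAR1 were then followed into the combined knockdown. Of the 4365 genes that fell with siADAR1, 2173 (49.8%) rose when the Staufen1 siRNA was added and 345 fell further. Of the 4847 genes that rose, 2121 (43.8%) fell and 363 rose further. The 708 genes that moved further became fewer when a siADAR1 or combined knockdown library was left out. They became more numerous when a siControl library was left out. Independent lists would hold 941 genes that fell further and 1053 that rose further. Lists drawn independently would share 948 and 1044 genes in the opposite directions. Among the 5499 genes not called with siADAR1, 660 rose and 704 fell when the Staufen1 siRNA was added. Scaled to library totals, 1200 genes fell and then rose, against 360 in independent lists, and 3557 rose and then fell, against 2127.

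As a set, the 4365 genes lower with siADAR1 had a median log2 fold change of -0.59 against siControl with siADAR1 and -0.37 with the combined knockdown, and 77.5% of them lay closer to siControl in the latter. The 4847 higher genes had medians of 0.86 and 0.59, and 73.7% lay closer. Measured per library from the siControl mean, the lower set stood at -0.58 ± 0.0078 in siADAR1 and -0.37 ± 0.0077 in the combined knockdown, and the higher set at 0.85 ± 0.011 and 0.59 ± 0.00081 (SD, n = 2 each). The sets were chosen on these same siControl and siADAR1 libraries. Under library totals, medians of the same genes were -0.29 and -0.19 for the lower set and 1.15 and 0.78 for the higher set, and 57.0% and 84.8% lay closer to siControl.

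**Figure D3:**
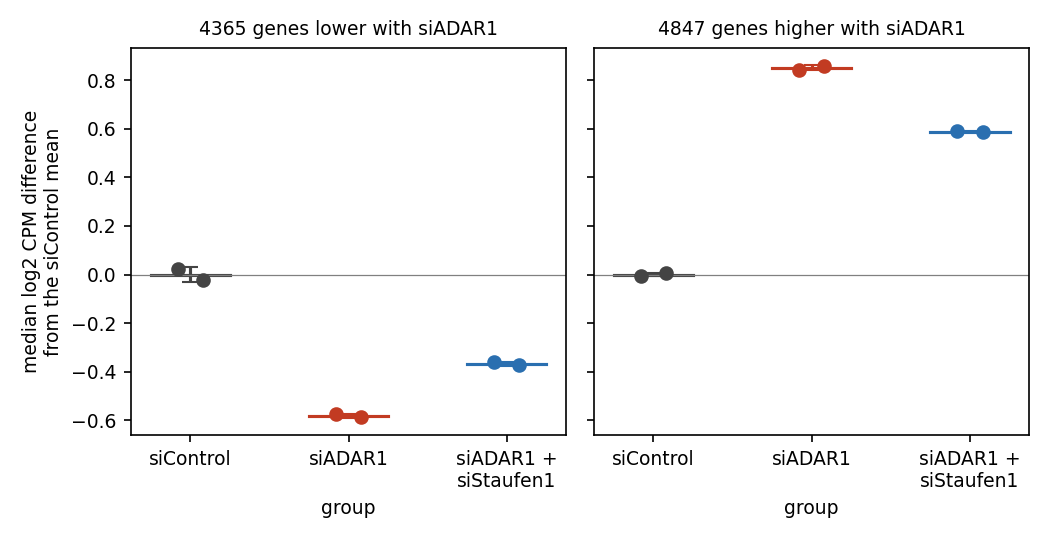
Median log2 CPM difference from the siControl mean over the 4365 genes lower and the 4847 genes higher with siADAR1, with 1 point per library, a bar at the group mean and the SD of the 2 libraries as error bars. The combined knockdown lies between siControl and siADAR1 in both sets, at -0.37 and 0.59 against -0.58 and 0.85.

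The return towards siControl was often partial. Of the 2173 genes that fell and then rose, 1103 (50.8%) were still lower than siControl in the combined knockdown, 926 (42.6%) were no longer called against siControl and 144 (6.63%) were higher. Their median log2 fold changes were -0.70 with siADAR1, -0.22 with the combined knockdown and 0.46 between these. Of the 2121 genes that rose and then fell, 1056 (49.8%) were still higher, 872 (41.1%) were no longer called and 193 (9.10%) were lower. Their medians were 0.95, 0.30 and -0.57. A missed threshold does not show that a gene had returned to its siControl level.

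Both comparisons behind these counts use the siADAR1 libraries with opposite sign, so chance alone ties them together. Simulated data without effects gave at most 3 genes that fell and then rose in any of 100 data sets, and at most 2 that rose and then fell. Such data hold few calls at all (means of 3.44 and 3.11 genes in these comparisons). These counts therefore do not measure the tie among the many genes called here. Across genes, the covariance of the log2 fold changes was -0.265 against a simulated -0.0228, a difference of -0.242. The correlation was -0.535 against a simulated -0.481. In the simulated data all variation is noise, so these correlations do not show what share of the slope is chance.

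**Figure D4:**
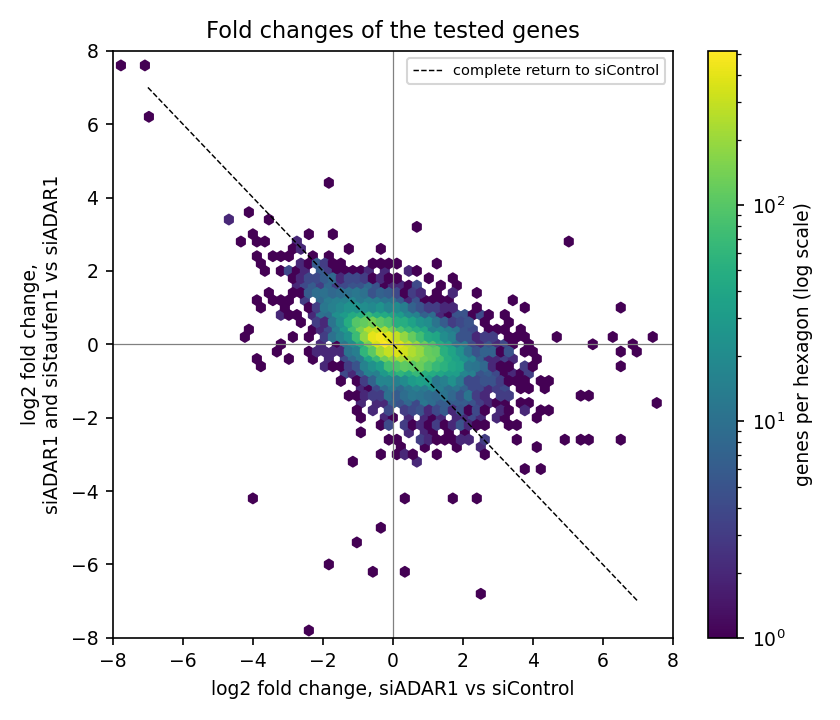
Log2 fold change of the combined knockdown against siADAR1 (vertical axis) and of siADAR1 against siControl (horizontal axis) for the tested genes, shaded by the number of genes per hexagon on a log scale. The dashed line marks a complete return to siControl, and the cloud slopes downwards less steeply than this line. The correlation across genes is -0.535. Simulated data without effects, where all variation is noise, gave -0.481, but their covariance was -0.0228 against -0.265 here.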

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

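Thinning and the normalization against abundance were chosen after seeing the data, as was the count of genes that moved further from siControl. Of 132 alternative counts of changed genes, 122 lay within 1.5 times the reported count. Under library totals, 2406 genes fell with siADAR1 and 2349 with the combined knockdown, 1200 fell with siADAR1 and then rose, and 3557 rose and then fell. With glmTreat at 1.5-fold, 2296 rose and 1307 fell with siADAR1, 1544 rose and 711 fell with the combined knockdown against siControl, and 448 rose and 571 fell against siADAR1. The glmTreat counts are lower by construction, since that test asks for a larger change. For library totals, the shift of all fold changes moves genes across 0. DESeq2 called 3986 rises and 4117 falls for siADAR1, and thinning 4718 and 4253.

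With each library left out in turn, where the lone sample of a group is assumed to vary like the other groups, siADAR1 gave 4067 to 4705 rises and 3666 to 4307 falls against siControl. The combined knockdown gave 3374 to 4021 rises and 3076 to 3857 falls against siControl, and 2206 to 3659 rises and 2221 to 3746 falls against siADAR1. Genes that fell and then rose numbered 1537 to 2393, and genes that rose and then fell 1441 to 2387. With the replicate block, 4858 genes rose and 4378 fell with siADAR1. The deviations of libraries with the same letter correlated by 0.051, 0.021 and 0.0060 across genes, so the letters were not taken to pair the libraries. Of 252 alternative values for single genes, 251 stayed on their side of the threshold, and uc002xua.3 with siADAR1 alone lost its call under glmTreat. The 4 genes printed by ID were picked for the largest changes, so this count says little about other genes. LINC01426, never called, ranged from -0.29 to 0.85 on the log2 scale for the combined knockdown against siControl when a library was left out, with siControl replicates b and a giving the ends. The gene list tests and their alternatives were not run, since no annotation linking the UCSC IDs to gene symbols was used here.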

Other observations

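The tests of the shared siADAR1 libraries and of a uniformly weaker ADAR1 effect were chosen after the result was seen, and those by thinning and by normalization against abundance were chosen after seeing the data. Recovery towards siControl was measured for the large falls and the large rises with siADAR1. It was taken as the opposite log2 change in the combined knockdown, as a percent of the log2 change with siADAR1. Over the 890 genes that fell at least 2-fold its median was 50.7% (quartiles 29.1% and 71.0%), and 602 of them (67.6%) rose again by edgeR's quasi-likelihood test. Over the 1978 genes that rose at least 2-fold it was 27.2% (quartiles 7.72% and 48.4%), and 1000 (50.6%) fell again. Recovery stayed under 10% for 107 (12.0%) of the falls and 549 (27.8%) of the rises. Under library totals the medians for the same genes were 54.5% and 29.1%, but the shares that moved back were 61.0% and 60.3%, so the difference in shares depended on the scaling. The difference between the directions was not tested, and genes picked for large changes in these siADAR1 libraries can show some recovery by chance.

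The genes with large changes on adding the Staufen1 siRNA were also traced back to siADAR1 alone, which raised 32.9% and lowered 29.7% of all tested genes. Of the 562 genes that fell at least 2-fold against siADAR1, 398 (70.8%) had risen with siADAR1, 125 (22.2%) had not been called and 39 (6.94%) had fallen. Of the 467 genes that rose at least 2-fold, 316 (67.7%) had fallen, 123 (26.3%) had not been called and 28 had risen. Both comparisons use the siADAR1 libraries with opposite sign, which favours such opposite calls. With a different siADAR1 library for each comparison, 63.5% or 62.9% of the large falls had risen, against 27.8% and 27.1% of all genes, and 62.4% or 68.1% of the large rises had fallen, against 25.1% and 24.5%. Under library totals, 587 of 733 large falls (80.1%) had risen, against 48.2% of all genes, and 232 of 361 large rises (64.3%) had fallen, against 16.4%. All 10 of the genes with the largest falls with siADAR1 rose again, by 0.22 to 3.47 on the log2 scale, and all 10 remained lower than siControl. The gene that rose by 0.22 had changed by -4.28 with siADAR1, so not every return was large. Of the 10 largest rises, 7 fell again, 1 rose further and 2 were not called.

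The 4 rows matched through synonyms in the RefSeq table hold long non-coding RNAs and were the only matches, so they were chosen after the files were seen. LINC01426 had 18 and 10 reads in siControl, 27 and 35 in siADAR1 and 21 and 23 in the combined knockdown. Its log2 fold change was 0.54 (SE 0.42) with siADAR1, with an adjusted p of 0.277 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and both siADAR1 libraries lay above the siControl mean but not both above the higher siControl library. This value rests on single siControl libraries, as it was 1.18 without siControl replicate a and 0.03 without replicate b, not called in either case. ACTA2-AS1, the match with its version number, had at most 4 reads in any library, MIR7-3HG at most 2 and ZNF350-AS1 had 0 in every library, which allows up to 3 reads each, for counting error only.

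More genes were detected in both knockdown groups than in siControl, and the reads were less concentrated on abundant genes. Library depth alone would remove the gap once the libraries hold the same number of reads, yet after thinning the lowest knockdown library still exceeded the highest siControl library by 284 genes with at least 10 reads, against a difference of 9 between the siControl libraries. Without the 100 most abundant genes, and thinned again, the gap was 180 genes, against 17 between the siControl libraries, so those genes do not account for all of it. The gap may reflect a broader set of transcripts in the cells given the ADAR1 siRNA, a hypothesis found on these same data and not itself tested. A difference in the cells that received the ADAR1 siRNA, or in the library preparation of the groups, stays open as untested.

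The genes that moved with siADAR1 moved back in part when the Staufen1 siRNA was added. Chance variation of single siADAR1 libraries would no longer tie the comparisons with a separate siADAR1 library for each. The covariance then averaged -0.242 (-0.247 and -0.237), below the lowest of 100 simulated data sets without effects (-0.0036 and -0.0041). A deviation common to both siADAR1 libraries would remain after this split and was not simulated, so it stays open. With each library normalized against abundance, 3965 genes moved back (2068 that fell and 1897 that rose), where 4294 did without it. This argues against a trend with abundance as the whole cause. Independent lists give 1861 after it, but they ignore the tie through the shared siADAR1 libraries, which this normalization leaves in place. If the ADAR1 siRNA had only acted more weakly by the same factor for every gene, and nothing else had changed, genes moving further from siControl would be false calls. At an adjusted p under 0.001 for the combined knockdown against siADAR1 (edgeR, Benjamini-Hochberg), 261 of 2621 calls had moved further. The call with siADAR1 stayed at the threshold of 0.05. The threshold of 0.001 itself allows 2.62. The larger of 2 false shares in a single simulation (4 of 114 calls for siADAR1 against siControl, 1 of 121 for this comparison) gives about 92.0. The Staufen1 siRNA can also move genes away from siControl by itself. An excess of such genes therefore cannot tell whether a uniformly weaker ADAR1 effect explains the moving back, and that explanation stays open. The 708 genes that moved further at the threshold of 0.05 decide nothing either. The simulated false shares there, 8.59% for this comparison and 13.2% for siADAR1 against siControl, would give 547 and 839. That simulation changed only 200 of 14711 genes, whereas 43.3% of the genes tested were called in this comparison. None of its false shares, at either threshold, need hold for the real calls. A weaker ADAR1 knockdown, the same for every gene or differing between genes, may still be part or all of the moving back. An effect of Staufen1 itself or of adding a further siRNA was not tested. The levels of ADAR and STAU1, which bear on these explanations, were not analysed here.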
